A study of Mus musculus with 5 samples.

How the data were processed

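Bulk RNA sequencing was carried out on amygdala astrocytes of CCR2-DTR mice, which carry a tamoxifen-inducible Cre recombinase at the Ccr2 locus and a Cre-dependent diphtheria toxin receptor. Per the labels' protocols, the mice received tamoxifen and either saline or DTx during 18 days of tube restraint, and fear conditioning and extinction followed. Tissue was digested with papain, astrocytes were collected on magnetic beads against ACSA-2, and 5 ng of total RNA went into each library. The 5 libraries analysed here were 2 saline and 3 DTx libraries. The series' design text gives 3 saline animals, and the remaining saline library is not analysed here.

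The authors deposited a table of raw read counts per gene, with a column for each library and no pooling. Per the submitters' processing notes, the tools were fastp 0.23.2, FastQC 0.11.9, MultiQC 1.11, STAR 2.7.5c, featureCounts 2.0.1 and edgeR 3.42.4, and the builds were GRCm38 and mm10. Their settings, the gene annotation and whether counting used the strand are not given in the sources used here, so counts of overlapping antisense genes such as Xist and Tsix cannot be told apart. The deposited counts were whole numbers with totals of 15961220 to 23720299 per library over 35976 genes. Saline columns were assigned by the word Ctrl and their number to saline replicates 1 and 2. The DTx columns carry numbers found in no label, so they were assigned to the group alone and are called DTx libraries 5A, 6A and 7A. There was 1 further column of per-sample values, which was not used in any step.

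Gene symbols were matched to a RefSeq table of GRCm38.p6, which held 32501 of the 35976 symbols, and chromosomes and positions come from that table. The 13 mitochondrial symbols of the fixed list are spelled without their prefix in the deposited table and were respelled. No pair of libraries agreed within sampling noise, since a chi-square test of the counts of each pair, over genes with at least 20 counts in the pair, gave at least 14.25 per degree of freedom. The labels number the libraries within each group without saying that each number is a separate animal, so p-values measure the spread between these libraries.

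Genes were compared between the DTx-labelled and saline libraries with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr by group with a minimum count of 10, and the robust quasi-likelihood F test with Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05, and fold changes are DTx over saline. Levels are TMM-scaled counts-per-million (CPM) values, given as mean ± SD. A group with no count was set to a floor of 3 counts over the group, and a group with 1 to 3 counts is given as a ratio of summed counts with a 95% exact interval. These bounds and intervals come from counts summed over each group, so they cover counting error only and not the spread between libraries. The reads also carry no stated molecular identifiers.

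Before the data were examined, 40 gene lists were fixed. They covered other brain and blood cell types, astrocyte functions, stress and immune pathways, and RNA quality, and 37 had at least 5 genes tested. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The test was repeated with a correlation estimated per list and with fry. For each list, members were also adjusted over the list alone. Single values per library were compared with a two-sided exact permutation test over all 10 regroupings of 5 libraries into 3 and 2, whose smallest possible p is 0.1.

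The genes named in the text followed a rule fixed before the data were examined. Ccr2 and Hbegf were always named. In each direction, up to 15 genes past the threshold were to be named if their mean was at least 1 CPM, their groups did not overlap and they had a proper gene name. Where fewer than 5 qualified, the genes with the smallest p were added up to 8 per direction, with their values. In each list described, up to 4 members with the smallest p were named, except that 3 such members are not reported here. A list was described if it passed its test, if at least 2 members passed over all genes, or if it marked another cell type or RNA quality. Other genes are named as chosen after their values were seen.

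The count test was tested on simulated data, with counts drawn for the 15532 genes tested from the means and library sizes of this comparison and 200 changed genes in each of 5 runs. It called 28.7% of genes changed 2-fold, 69.4% of those changed 4-fold and 88.1% of those changed 8-fold, and 69 of 75142 unchanged genes. Of simulated lists of 25 genes, 5 of 5 raised 1.5-fold and 0 of 100 unchanged lists were called. These simulated genes varied independently of each other, unlike the genes of several real lists.

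Alternatives fixed before the data were examined were RLE, upper-quartile and total-count scaling, other low-count filters, each library left out, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, the legacy quasi-likelihood method, no robust step, a threshold of 0.1 and a minimum log2 fold change of 1. For lists they were the estimated correlation, fry, lists without shared members, and prior counts of 0.5 and 5. Alternatives added after seeing the data left out genes on chromosomes X and Y or used the mean of the ependymal or microglia markers as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.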

Results

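The experiment asked how depletion of CCR2-expressing monocytes during chronic restraint stress changed astrocytes of the basolateral amygdala. ACSA-2-selected cells of 2 saline libraries and 3 libraries labelled DTx (diphtheria toxin) were compared by RNA sequencing. Total counts were 20577672 and 23720299 in saline replicates 1 and 2, and 17788200, 15961220 and 18708138 in DTx libraries 5A, 6A and 7A. Between 20409 and 21800 genes had a count in each library. The leading principal component carried 45.4% of the variance and did not separate the groups, with scores of -54.0 and 45.95 in the saline libraries and -40.44, 7.19 and 41.29 in DTx libraries 5A, 6A and 7A. The next component carried 32.1%, with -48.38 and -23.77 in the saline libraries and 38.84, 38.83 and -5.53 in the same DTx libraries. The groups did not overlap on it.

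Ccr2, the chemokine receptor whose locus drives the Cre recombinase of these mice (GRCm38 chromosome 9, 124101918 to 124109140), had 0 counts in both saline libraries and 62 counts in the 3 libraries labelled DTx. Its levels there were 2.85, 0.249 and 0.228 CPM in libraries 5A, 6A and 7A. The summed level was at least 17.3-fold higher in the libraries labelled DTx, which is opposite to the depletion that the label names, and the gene fell below the filter of the count test. Of the 62 counts 54 were in library 5A. The level was at least 3.49-fold higher without it, from 8 counts, and at least 8.77-fold and 8.52-fold higher without saline replicates 1 and 2. Hbegf, the mouse gene of the protein that serves as the diphtheria toxin receptor in other species (chromosome 18, 36504927 to 36515805), stood at 58.96 ± 7.78 CPM (SD, n = 2) in saline and 53.61 ± 7.93 CPM (SD, n = 3) in DTx-labelled libraries, with an edgeR adjusted p of 0.877. These Ccr2 counts cannot decide whether the labels are right. The cells were selected as astrocytes, saline had no count from which a fall could be seen, and most counts lay in library 5A. Every direction below is that of the libraries as labelled.

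Genes of the sex chromosomes separated the groups completely. Xist, the long noncoding RNA that silences an X chromosome in female cells (chromosome X, 103460373 to 103483233), fell from 150.8 ± 30.9 CPM (SD, n = 2) in saline to 0.0529 ± 0.0916 CPM (SD, n = 3), with 6615 counts against 3. The ratio of counts, saline over DTx, was 2640 (95% interval 901 to 12800), and the edgeR adjusted p was 5.51e-06. Ddx3y, a Y-linked RNA helicase (chromosome Y, 1260715 to 1286628), rose from 0.115 ± 0.0989 to 124.3 ± 9.56 CPM, a log2 fold change of 10.01 ± 0.338 (SE, adjusted p = 5.45e-05). Eif2s3y, a Y-linked subunit of translation initiation factor 2 (chromosome Y, 1010562 to 1049134), rose to 39.25 ± 3.78 CPM with a count ratio of 1730 (95% interval 311 to 68500, adjusted p = 0.000133). Uty and Kdm5d, Y-linked histone demethylase family members at 1085187 to 1245773 and 897566 to 943813, had no count in saline. They rose to 15.64 ± 1.34 and 16.58 ± 2.54 CPM, at least 229-fold and 244-fold higher, with adjusted p of 0.00845 and 0.011. Summed over these 4 Y-linked genes, the level was 0.185 and 0.0897 CPM in saline and 201.2, 185.4 and 200.6 CPM in the DTx-labelled libraries, so the state of the sex chromosomes and the treatment label coincided in 5 of 5 libraries.

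**Figure D1:**
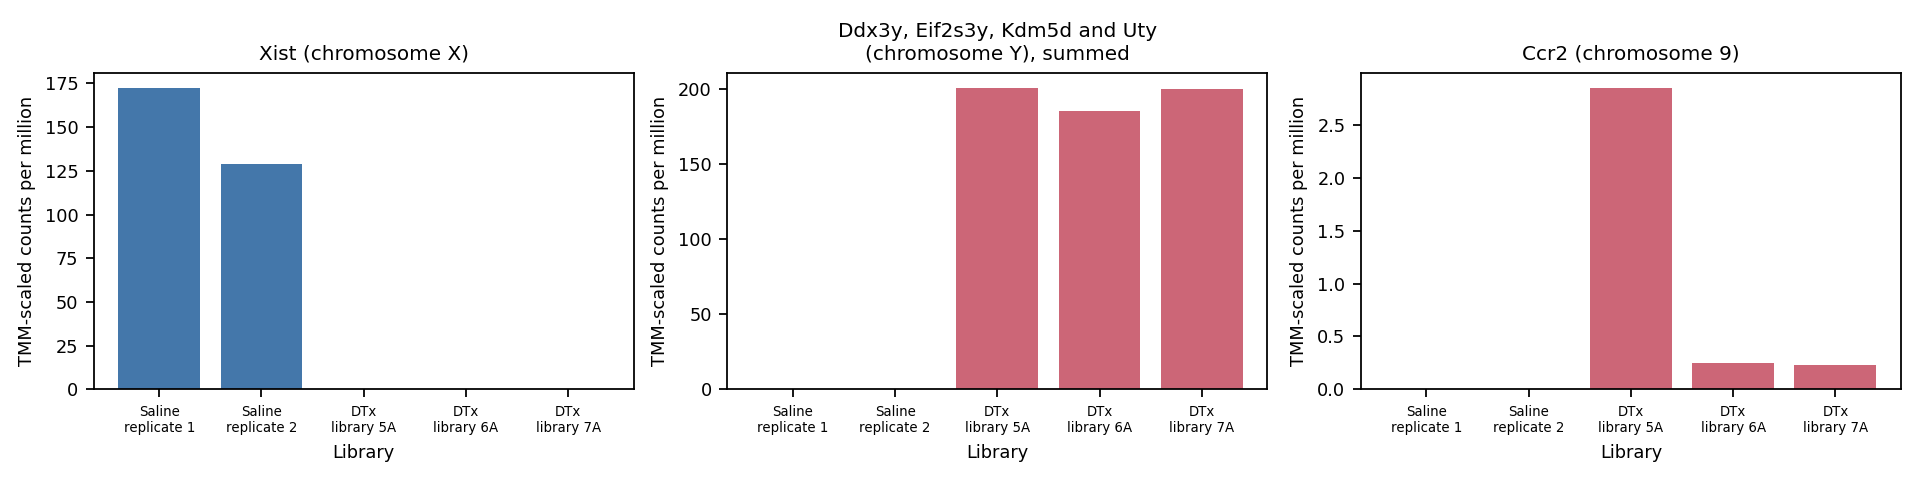
TMM-scaled CPM of Xist, of the sum of Ddx3y, Eif2s3y, Kdm5d and Uty, and of Ccr2 in each library; bars are single libraries, blue for saline and red for DTx. Xist was 172.6 and 128.9 CPM in saline and at most 0.159 CPM in the DTx-labelled libraries, the Y-linked sum was at least 185.4 CPM in the latter, and Ccr2 reached 2.85 CPM in DTx library 5A.

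These 5 genes, 4 higher and 1 lower, were the ones that passed among 15532 tested with edgeR's quasi-likelihood test, and none lay outside chromosomes X and Y, where the smallest adjusted p was 0.611. At an unadjusted p under 0.05 there were 1038 genes, 698 higher and 340 lower, against 777 given by chance. Outside chromosomes X and Y, limma-voom called 0 genes, DESeq2 called 94 and the edgeR likelihood ratio test called 83. Without DTx library 6A 3 genes passed, and without library 7A 13 passed, 6 of them outside chromosomes X and Y. Without saline replicate 2, 1 gene outside these chromosomes passed. Values of the 2 groups did not overlap in 12.1% of genes with DTx higher and 8.99% with DTx lower, where chance gives 10% for each.

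The genes with the smallest p after these did not pass the threshold. Among those higher in the DTx-labelled libraries, Uba1y, a Y-linked ubiquitin-activating enzyme, was at 1.74 ± 0.163 CPM (SD, n = 3) against no count in saline (at least 25.7-fold higher, adjusted p = 0.597). Pmch, the precursor of melanin-concentrating hormone, was at 5.55 ± 0.827 against 1.34 ± 0.0686 CPM (adjusted p = 0.611). Gpx3, an extracellular glutathione peroxidase, was at 25.48 ± 7.3 against 6.77 ± 1.02 CPM (adjusted p = 0.638), and Hpcal1, a neuronal calcium sensor, at 14.54 ± 0.865 against 6.94 ± 0.209 CPM (adjusted p = 0.734). Among those lower, Tsix, the antisense partner of Xist, had 1 count against 85, and its reads overlap those of Xist, so its value is uncertain. Arc, an activity-induced synaptic gene, was at 25.88 ± 8.15 against 77.68 ± 11.1 CPM, a log2 fold change of -1.59 ± 0.264 (SE). Kdm6a, an X-linked histone demethylase that escapes X inactivation, was at 25.17 ± 3.63 against 47.66 ± 3.67 CPM. Sod3, the extracellular superoxide dismutase, was at 37.35 ± 2.23 against 64.99 ± 4.8 CPM, and the log2 fold changes of Phlda1, Btbd17 and Zdhhc14 were -0.92, -0.87 and -1.02. The adjusted p of Tsix was 0.375, and that of the other 6 lower genes was 0.734.

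The gene lists asked which astrocyte programmes, immune responses and other cell types differed between the groups. Of 37 lists tested, 16 passed camera of limma with the preset correlation, 14 higher and 2 lower in the DTx-labelled libraries. With an estimated correlation 0 lists passed (1 at an unadjusted p under 0.05), and with fry 0 passed (5 at an unadjusted p under 0.05). Without saline replicate 1, 10 lists were higher and 6 lower, with 10 of the 16 shared with the reported ones. Without saline replicate 2, 16 were higher and 3 lower (13 shared), and without DTx library 7A 10 were higher and 2 lower (12 shared). With the microglia marker mean as a covariate 9 were higher and 7 lower (9 shared). Other splits of the same 5 libraries into 3 and 2 called 11 to 16 lists with the preset correlation.

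Type I interferon response genes had the highest list median. All 29 members tested were higher in the DTx-labelled libraries, 27 of them without overlap between groups, with a median log2 fold change of 2.27, or 4.83-fold. The median stayed at 2.27 with the member that had no saline count at its bound. The list passed with adjusted p = 9.55e-22. It did not pass with an estimated correlation, which was 0.709 for this list (adjusted p = 0.572). Adjusted over the list alone 25 members passed, and 0 passed over all genes, where DESeq2 called 13 and the edgeR likelihood ratio test 15. Irf9, a subunit of the interferon-stimulated transcription factor complex, was at 8.61 ± 0.689 CPM (SD, n = 2) in saline and 30.99 ± 12.7 CPM (SD, n = 3) in the DTx-labelled libraries, with an edgeR adjusted p of 0.0183 over the list alone. Irf7, an interferon-induced regulator of interferon transcription, was at 1.12 ± 0.506 and 14.44 ± 10.1 CPM, Trim30a at 1.27 ± 0.102 and 7.97 ± 3.93 CPM, and Oas1a, a sensor of double-stranded RNA, at 0.159 ± 0.0289 and 2.52 ± 1.4 CPM. The mean log2 CPM of the list was 1.47 and 1.69 in saline and 3.78, 4.34 and 2.71 in DTx libraries 5A, 6A and 7A (exact permutation p = 0.2). The list also separated DTx libraries 5A and 6A from the other 3 libraries. It was lower in those 3, with a median log2 fold change of -2.15 (camera adjusted p = 1.06e-17, and adjusted p = 0.801 with an estimated correlation and 0.181 with fry).

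**Figure D2:**
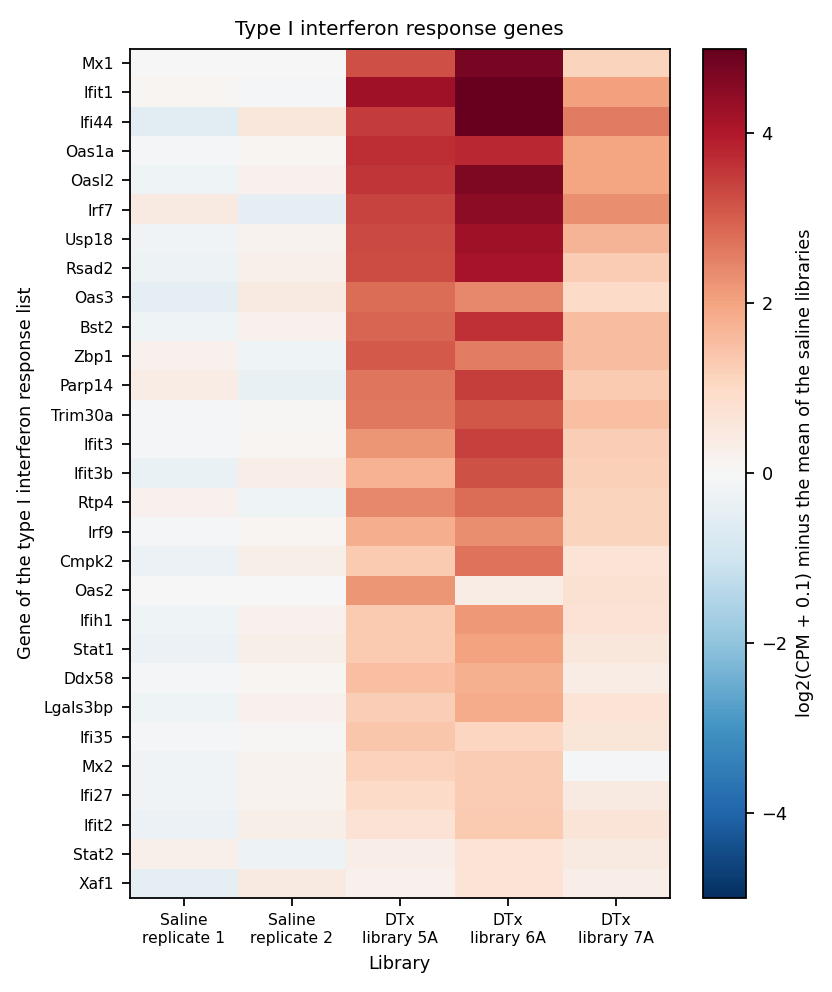
Heat map of the 29 tested genes of the type I interferon list in each library, as log2(CPM + 0.1) minus the mean of the saline libraries. All 29 genes were higher on average in the DTx-labelled libraries, with the list mean at 4.34 log2 CPM in DTx library 6A and 2.71 in library 7A.

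Type II interferon and antigen presentation genes were higher for 25 of 25 members, with a median log2 fold change of 1.60. The list passed with adjusted p = 7.57e-15 but not with an estimated correlation (adjusted p = 0.572), and 20 members passed adjusted over the list alone against 0 over all genes, where DESeq2 called 7 and the likelihood ratio test 2. Psmb8 and Psmb9, catalytic subunits of the immunoproteasome, were at 2.97 ± 0.742 and 0.707 ± 0.176 CPM in saline (SD, n = 2) and 14.55 ± 6.16 and 2.37 ± 0.688 CPM in the DTx-labelled libraries (SD, n = 3). Gbp3 and Irgm1, interferon-induced GTPases, were at 6.14 ± 0.194 and 7.4 ± 3.22 CPM in saline and 31.39 ± 20.7 and 22.5 ± 8.61 CPM in the DTx-labelled libraries. In these same libraries the mean log2 CPM of microglia markers was 2.32 and 3.84 in saline and 4.53, 4.08 and 3.73 in DTx libraries 5A, 6A and 7A, and saline replicate 2 lay above library 7A.

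Of the reactive astrocyte lists, the LPS-type and shared ones passed with the preset correlation, and differences between lists were not tested. Of the LPS-type reactive list, 11 of 12 members were higher, with a median log2 fold change of 1.83 (adjusted p = 3.69e-07, and adjusted p = 0.572 with an estimated correlation). Adjusted over the list alone 9 of its members passed, and 0 over all genes, and the median was 1.01 with the microglia marker mean as a covariate. The members with the smallest p, Psmb8, H2-T23, Iigp1 and H2-D1, are interferon-inducible, and Iigp1 was at 0.454 ± 0.0549 CPM (SD, n = 2) in saline and 10.11 ± 8.8 CPM (SD, n = 3) in the DTx-labelled libraries. H2-T23 and H2-D1, genes of major histocompatibility complex class I, were at 0.48 ± 0.235 and 72.81 ± 17.5 CPM in saline and 4.17 ± 2.69 and 153.9 ± 55.2 CPM in the DTx-labelled libraries, and counts of such near-identical family members are uncertain.

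The shared reactive list was higher for 9 of 11 members, with a median of 1.02 (adjusted p = 0.000101, and adjusted p = 0.572 with an estimated correlation), and its median was 0.34 without DTx library 5A, 0.438 with no low-count filter and 0.654 with the microglia covariate. Adjusted over the list alone 1 member passed, Serpina3n, a serine protease inhibitor of reactive astrocytes, at 22.35 ± 0.724 CPM (SD, n = 2) and 49.92 ± 9.65 CPM (SD, n = 3), and 0 passed over all genes. Gfap, the intermediate filament of reactive astrocytes, was at 290.2 and 741 CPM in saline and 1079, 1132 and 1609 CPM in DTx libraries 5A, 6A and 7A. Osmr, the oncostatin M receptor, was at 1.47 ± 0.774 and 3.65 ± 0.331 CPM, and Timp1, a metalloproteinase inhibitor, at 0.181 ± 0.0606 and 0.767 ± 0.298 CPM. The list of cytokine receptors and STAT3 response, which shares Serpina3n, Osmr and Gfap and adds Cebpd, was higher for 13 of 25 members with a median of 0.07. It passed with adjusted p = 0.0304 but not with an estimated correlation (adjusted p = 0.584), with 1 member past the threshold adjusted over the list alone and 0 over all genes. Its call ended without library 5A (camera adjusted p = 0.0519), without library 7A (0.154) and with the microglia covariate (0.0982, where the median rose to 0.203). The call also ended without members shared with other lists (0.78, median -0.117). With a library left out the median of the list was 0.0747 (without 5A) to 0.272 (without saline replicate 1).

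Lists of inflammatory mediators had medians above 0. NF-kB and TNF response genes were higher for 21 of 26 members (median 0.53, adjusted p = 6.9e-06, and adjusted p = 0.52 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, had 2 counts in saline and 60 in the DTx-labelled libraries, a ratio of 25.1 (95% interval 6.65 to 212), and was the 1 member past the threshold adjusted over the list alone, with 0 over all genes. Icam1, an adhesion molecule, was at 0.518 ± 0.472 CPM (SD, n = 2) and 2.82 ± 0.858 CPM (SD, n = 3), Nfkbia, the NF-kB inhibitor, at 38.0 ± 14 and 76.43 ± 19 CPM, and Bcl3 at 0.181 ± 0.0606 and 0.714 ± 0.207 CPM. Without DTx library 5A, 6A or 7A the median of this list was 0.251, 0.346 or 0.356, without saline replicate 2 it was 0.819, with genes of at least 1 CPM in 2 samples it was 0.302, and without members shared with other lists it was 0.275.

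Chemokine and cytokine genes were higher for 20 of 25 members (median 1.39, adjusted p = 5.51e-05, and adjusted p = 0.572 with an estimated correlation), with 0 members past the threshold adjusted over the list alone and 0 over all genes. Ccl3 and Ccl4, chemokines made by activated macrophages, were at 0.091 ± 0.0019 and 0.316 ± 0.251 CPM (SD, n = 2) and 1.44 ± 0.815 and 3.4 ± 2.27 CPM (SD, n = 3). Ccl12, a ligand of CCR2, was at 1.02 and 0.762 CPM in saline and 28.97, 3.61 and 7.58 CPM in DTx libraries 5A, 6A and 7A. Ccl5 had no count in saline and was at least 22.0-fold higher. The median of this list was 0.443, 0.564 and 0.557 without DTx libraries 5A, 6A and 7A, 0.842 without saline replicate 1 and 2.35 without saline replicate 2. The call ended with the microglia marker mean as a covariate (median 0.323, adjusted p = 0.097). Without members shared with other lists the median was 0.917, and with genes of at least 1 CPM in 2 samples it was 0.541. The summed level of the chemokine list ran the other way on average, at 1788 and 2136 CPM in saline and 1553, 1637 and 1958 CPM in DTx libraries 5A, 6A and 7A. With members that had no saline count at their bound, the medians of the NF-kB, chemokine and shared reactive lists stayed at 0.53, 1.39 and 1.02.

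Complement genes were higher for 10 of 15 members (median 0.76, adjusted p = 0.00511, and adjusted p = 0.584 with an estimated correlation), with 1 member past the threshold adjusted over the list alone and 0 over all genes. That member was C4b, a component of the classical pathway, at 20.94 ± 3.17 CPM (SD, n = 2) and 55.13 ± 16.3 CPM (SD, n = 3). C2 was at 15.02 ± 5.57 and 31.65 ± 7.83 CPM, and Serping1, the C1 inhibitor, at 4.01 ± 1.04 and 8.85 ± 3.58 CPM. The median of the list was 0.729 without saline replicate 1 and 1.47 without saline replicate 2. The call ended with the microglia marker mean as a covariate (median 0.288, camera adjusted p = 0.527). It also ended without members shared with other lists (median 0.225, adjusted p = 0.139).

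Glucocorticoid response genes were higher for 20 of 25 members (median 0.53, adjusted p = 0.000171, and adjusted p = 0.584 with an estimated correlation), with 0 past the threshold adjusted over the list alone and 0 over all genes. Sult1a1, a sulfotransferase, was at 17.34 ± 3.63 CPM (SD, n = 2) and 27.27 ± 3.12 CPM (SD, n = 3), Cebpd at 6.12 ± 2.38 and 11.49 ± 0.63 CPM, and Mt2, a metallothionein, at 95.47 ± 40.6 and 160.8 ± 18.8 CPM. The call ended without DTx library 7A (median 0.233, adjusted p = 0.083) and without members shared with other lists (median 0.338, adjusted p = 0.0712).

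Markers of other brain cells were also among the lists that passed. Microglia markers were higher for 19 of 20 members (median 0.90, adjusted p = 4.02e-07, and adjusted p = 0.602 with an estimated correlation). C1qc, a chain of complement C1q, was at 22.32 ± 12.6 CPM (SD, n = 2) and 51.55 ± 21.2 CPM (SD, n = 3), Laptm5 at 12.73 ± 6.91 and 24.05 ± 6.03 CPM, Trem2 at 3.05 ± 1.9 and 6.67 ± 2.33 CPM, and Aif1 at 2.94 ± 1.8 and 6.66 ± 3.09 CPM. The microglia call ended without saline replicate 1 (median 0.399, adjusted p = 0.204), and the median was 1.92 without saline replicate 2. Monocyte and border macrophage markers were higher for 12 of 13 members (median 1.79, adjusted p = 0.00259, and adjusted p = 0.672 with an estimated correlation). Their mean log2 CPM was 0.883 and 1.44 in saline and 3.45, 1.05 and 2.35 in DTx libraries 5A, 6A and 7A. Lyz2, the myeloid lysozyme, was at 6.42 and 9.82 CPM in saline and 91.28, 9.76 and 29.17 CPM in the same 3 libraries, Cybb at 1.18 ± 0.619 and 7.78 ± 6.02 CPM, Ms4a6c at 0.723 ± 0.5 and 5.0 ± 4.81 CPM, and Ms4a7 at 0.775 ± 0.145 and 3.13 ± 2.66 CPM. The median of this list was 0.513 without DTx library 5A and 1.55 without saline replicate 1. The call ended without library 7A, where the median was 1.93 (camera adjusted p = 0.0551). It also ended with the microglia marker mean as a covariate (median 0.787, adjusted p = 0.408). Adjusted over the list alone and over all genes, 0 members of either list passed.

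Neuronal markers were higher for 20 of 22 members (median 0.69, adjusted p = 6.53e-05, and adjusted p = 0.584 with an estimated correlation). Of these members 1 passed adjusted over the list alone and 0 over all genes. Stmn2 and Stmn3, microtubule regulators of neurons, were at 18.38 ± 0.132 and 22.84 ± 0.283 CPM in saline (SD, n = 2) and 34.42 ± 8.57 and 36.32 ± 9.27 CPM in the DTx-labelled libraries (SD, n = 3), and Celf4 at 126.0 ± 29.1 and 246.6 ± 75.5 CPM. The call ended without saline replicate 2 (median 0.455, adjusted p = 0.114).

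Oligodendrocyte markers were lower for all 17 members tested, with a median log2 fold change of -0.55 (adjusted p = 7.91e-06, and adjusted p = 0.602 with an estimated correlation). The mean log2 CPM was 10.1 and 10.6 in saline and 9.42, 9.37 and 10.4 in DTx libraries 5A, 6A and 7A. Ugt8a, an enzyme of myelin galactolipid synthesis, was at 360.7 ± 13.7 CPM (SD, n = 2) and 192.4 ± 49.5 CPM (SD, n = 3), Gjb1 at 198.3 ± 28.6 and 96.97 ± 55.9 CPM, Enpp2 at 1780.0 ± 209 and 1098.0 ± 451 CPM, and Trf, transferrin, at 7011.0 ± 183 and 4192.0 ± 1889 CPM. Oligodendrocyte precursor markers were higher for 3 of 13 members (median -0.39, adjusted p = 0.00582, and adjusted p = 0.629 with an estimated correlation). Olig2 and Sox10, transcription factors of the oligodendrocyte lineage, were at 89.92 ± 8.26 and 117.2 ± 1.64 CPM in saline and 57.15 ± 13.8 and 67.7 ± 34.1 CPM in the DTx-labelled libraries, Tnr at 10.73 ± 2.06 and 7.36 ± 0.837 CPM, and C1ql1 at 3.48 ± 2.71 and 1.52 ± 0.688 CPM. Adjusted over the list alone and over all genes, 0 members of either list passed. Without saline replicate 2 the medians were -0.118 and -0.264 and both calls ended (adjusted p = 0.0968 and 0.15). The precursor call also ended without library 5A (adjusted p = 0.13) and with the microglia covariate (median -0.16, adjusted p = 0.386). Without library 7A the medians were -0.952 and -0.64, and without library 6A the oligodendrocyte median was -0.343.

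**Figure D3:**
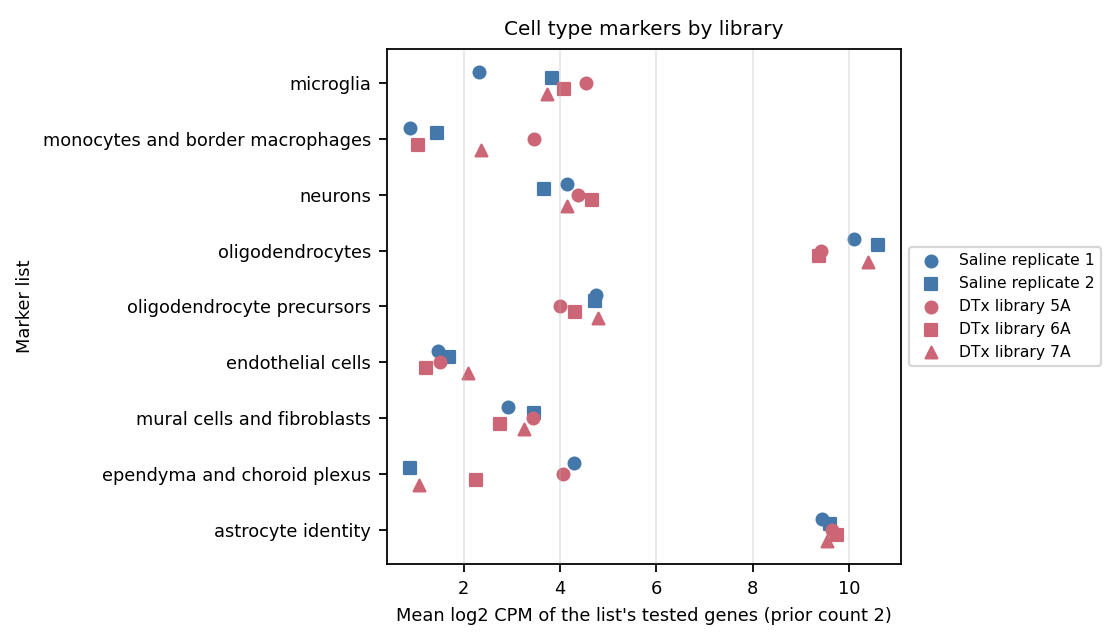
Mean log2 CPM (prior count 2) of the tested genes of each cell type list, with a point for each library, blue for saline and red for DTx. Microglia markers ran from 2.32 in saline replicate 1 to 4.53 in DTx library 5A, and astrocyte identity genes lay between 9.44 and 9.74 in the 5 libraries.

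The remaining cell type lists did not pass. Ependyma and choroid plexus markers varied within both groups, at a mean log2 CPM of 4.28 and 0.89 in saline and 4.06, 2.26 and 1.07 in DTx libraries 5A, 6A and 7A (median log2 fold change -0.57, adjusted p = 0.793). Clic6 was at 8.81 ± 0.73 CPM (SD, n = 2) and 57.69 ± 41 CPM (SD, n = 3), Otx2 at 16.74 ± 4.21 and 8.33 ± 2.96 CPM, Prlr at 3.06 ± 0.707 and 4.4 ± 1.13 CPM, and Foxj1, the master regulator of motile cilia, at 79.37 and 14.61 CPM in saline and 18.76, 11.26 and 17.89 CPM in libraries 5A, 6A and 7A. Without saline replicate 1 this list's median turned to 2.51 (adjusted p = 0.0375), and without saline replicate 2 it was -1.24 (adjusted p = 0.0341). Endothelial markers had a median of -0.04 and a mean of 0.10 with the test pointing up (adjusted p = 0.858), and mural and fibroblast markers a median of -0.03 (adjusted p = 0.602). The mural list passed without saline replicate 1 (median -0.201, adjusted p = 0.00442) and with the microglia covariate (median -0.255, adjusted p = 0.00317). Among endothelial genes, Ly6a was at 0.617 ± 0.238 and 1.64 ± 0.364 CPM, Kdr at 8.81 ± 0.537 and 5.68 ± 1.26 CPM, Egfl7 at 2.21 ± 0.0782 and 3.52 ± 0.233 CPM, and Itm2a at 7.57 ± 2.87 and 11.52 ± 3.71 CPM. The log2 fold changes of Col1a1, Myh11, Acta2 and Lum, of mural cells and fibroblasts, were -0.50, -0.46, -0.79 and 0.50, with adjusted p between 0.779 and 0.873. Erythrocyte genes, with 4 tested, summed to 30.89 and 27.03 CPM in saline and 31.45, 24.88 and 27.51 CPM in libraries 5A, 6A and 7A. Hbb-bs, Hba-a1 and Hba-a2, globin genes that share reads with near-identical copies, had log2 fold changes of -0.76, -0.93 and -0.62, and that of Hba-a2 was -0.032 without saline replicate 1. Neutrophil genes had 5 to 17 summed counts per library, and lymphocyte genes 13 to 49, of which Lck was the 1 gene tested, at 0.39 ± 0.298 and 0.833 ± 0.434 CPM.

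RNA quality lists were higher in the DTx-labelled libraries. Transcripts of the mitochondrial genome were higher for 9 of 9 members tested (median 0.33, adjusted p = 0.00986, and adjusted p = 0.584 with an estimated correlation). Their share of counts was 6.25% and 5.81% in saline and 6.32%, 6.84% and 6.94% in DTx libraries 5A, 6A and 7A (exact permutation p = 0.2). ND5, a subunit of complex I, was at 2938.0 ± 259 CPM (SD, n = 2) and 4108.0 ± 565 CPM (SD, n = 3), and ND4L, ND6 and ND1 had log2 fold changes of 0.92, 0.33 and 0.39. The call ended without saline replicate 1 (median 0.0858, adjusted p = 0.193), without library 7A (median 0.224, adjusted p = 0.154), with no low-count filter (median 0.273, adjusted p = 0.0614) and with the microglia covariate (median 0.167, adjusted p = 0.0661). Cytosolic ribosomal protein genes were higher for 42 of 43 members (median 0.31, adjusted p = 3.69e-07, and adjusted p = 0.672 with an estimated correlation), with a mean log2 CPM of 5.53 and 6.22 in saline and 6.32, 6.26 and 6.1 in libraries 5A, 6A and 7A. Rps19, Rpl32 and Rps15 had log2 fold changes of 0.52, 0.41 and 0.32. Without saline replicate 1 the ribosomal direction turned (median -0.00223, adjusted p = 0.682). With the microglia covariate the median was -0.0618, and without saline replicate 2 the median was 0.689. Adjusted over the list alone and over all genes, 0 members of either list passed.

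Astrocyte identity genes were at similar levels in both groups. Of 32 members, 19 were higher in the DTx-labelled libraries, with a median log2 fold change of 0.03 and camera adjusted p = 0.524. The mean log2 CPM was 9.52 ± 0.12 (SD, n = 2) in saline and 9.64 ± 0.101 (SD, n = 3) in the DTx-labelled libraries. Oligodendrocyte marker means were higher in saline replicates 1 and 2 (10.1 and 10.6 against 9.44 and 9.61) and library 7A (10.4 against 9.54). They were lower in libraries 5A (9.42 against 9.64) and 6A (9.37 against 9.74). The libraries thus also held RNA of oligodendrocytes, and whether oligodendrocytes gave rise to any change was not tested. Chosen after their values were seen, Aldh1l1, a folate enzyme used as a pan-astrocyte marker, was at 285.0 ± 9.99 and 283.9 ± 21.1 CPM, Slc1a2, the main glutamate transporter, at 5412.0 ± 307 and 5323.0 ± 415 CPM, and Aqp4, the water channel of astrocyte endfeet, at 834.3 ± 83.3 and 665.1 ± 95 CPM. Glutamate and GABA handling genes had a median of -0.01, genes of potassium, water and calcium handling -0.17, secreted synapse factors 0.07, extracellular matrix genes -0.02 and ischaemia-type reactive genes 0.37, with adjusted p of 0.884, 0.0656, 0.794, 0.236 and 0.0572. Among metabolic lists, cholesterol synthesis had a median of -0.09, lipid handling 0.03, fatty acid oxidation 0.09, glycolysis 0.02 and nuclear-encoded oxidative phosphorylation 0.12, with adjusted p of 0.0595, 0.793, 0.236, 0.661 and 0.113. Immediate early genes had a median of -0.31, heat shock genes -0.15, unfolded protein response genes -0.07, clock genes 0.04, oxidative stress genes 0.10, cell cycle genes 0.11 and TGF-beta and BMP response genes 0.05, with adjusted p between 0.106 and 0.524.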

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

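Leaving out chromosomes X and Y, the marker covariates and counting outside X and Y were chosen after the data were seen. The count of 5 genes past the threshold was the same under the other scalings, low-count filters and thresholds, limma-voom, the legacy and non-robust methods and the ependymal covariate, and 5 genes were shared with the reported ones under each. DESeq2 called 111 genes (95 higher, 16 lower) and the edgeR likelihood ratio test 100 (86 higher, 14 lower), 94 and 83 of them outside X and Y, and the cause was not tested. The count was 3 with the microglia covariate, which leaves 2 residual degrees of freedom, and 0 of 14975 genes (967 at an unadjusted p under 0.05) with X and Y left out. Leaving out each library gave 3 genes (without 6A) to 13 (without 7A), and 0 to 6 outside X and Y, where 1 was called without saline replicate 2. Kdm5d missed the threshold without either saline library or library 6A, and Uty without library 6A (adjusted p 0.0562 to 0.0629). With 1 saline library left, that library is assumed to vary like the DTx libraries.

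The 16 list calls became 0 with an estimated correlation and 0 with fry, and ranged from 12 to 19 with each library left out. Of the 16 reported lists, 10 were shared without saline replicate 1 and 9 with the microglia covariate, each of which called 16. The direction of some values turned, and of these the ribosomal list had passed, as had the STAT3 list, whose median was -0.117 without shared members. The cause was not tested. With each library left out, log2 fold changes ranged from -0.27 to 0.0037 for Hbegf, -1.60 to 0.081 for Acta2, -0.12 to 0.88 for Lum and -2.31 to 0.13 for Foxj1, and list medians from -0.152 to 0.441 for endothelial cells, -0.201 to 0.467 for mural cells, -1.5 to 2.51 for ependyma and -0.00223 to 0.689 for ribosomal proteins. The endothelial median was -0.0536 without X and Y, -0.0376 with the ependymal covariate and 0.0655 with the microglia covariate, where the test's own direction turned. With the microglia covariate the ependymal median was 1.14 and the ribosomal one -0.0618 (adjusted p = 0.0415).

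No paired analysis was possible because the DTx columns carry no replicate number, so the planned replicate block was not run for genes or lists. The gene test called 28.7% of simulated 2-fold changes and 69.4% of 4-fold changes, and why so few genes passed was not tested. Ccr2 rested on 62 counts in all, 54 of them in library 5A.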

Other observations

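The tests of microglia, of monocytes and macrophages, of sex, of genes that escape X inactivation, of an exchanged library, of neurons of every region by the hypothalamic genes and of regional genes of at least 1 CPM were chosen after their results were seen. Those of hypothalamic tissue, of telencephalic against neuron list genes and of other splits were chosen before.

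Genes of hypothalamic neurons were not among the lists of the report. Of 26 tested, 24 were higher in the DTx-labelled libraries, with a median log2 fold change of 1.71 (3.03 without saline replicate 2 and 1.1 without library 5A), and of 15 genes of telencephalic excitatory neurons 11 were higher, with a median of 0.317 (0.153 without library 5A and 0.118 without library 6A). The mean log2 CPM of the hypothalamic list was 0.0475 and 0.752 in saline and 2.52, 2.22 and 1.18 in DTx libraries 5A, 6A and 7A. Of its 26 genes 23, 20 and 14 lay above both saline libraries in these 3, and 10 did so in all 3, among them the next 4. Named after their values were seen, Hcrt, the orexin precursor, was at 0.94 ± 0.695 CPM (SD, n = 2) and 3.33 ± 0.445 CPM (SD, n = 3), Gpr101 at 0.249 ± 0.0913 and 1.84 ± 0.767 CPM, Nkx2-1, a homeobox factor of the ventral forebrain, at 0.381 ± 0.539 and 6.13 ± 4.29 CPM, and Tac1, the substance P precursor, at 2.24 ± 1.01 and 5.12 ± 1.83 CPM. The most abundant of the list, Peg3, Ndn, Hap1 and Ddc, which other brain cells also express, were at 112.9 ± 16.4, 46.26 ± 6.46, 27.59 ± 20.1 and 43.19 ± 8.85 CPM and 138.0 ± 19.7, 65.84 ± 10.1, 49.78 ± 21.9 and 36.85 ± 21 CPM. Hcrt, Gpr101, Nkx2-1 and Tac1 did not pass over all genes with edgeR (adjusted p = 0.742, 0.734, 0.742 and 0.742). DESeq2 called Resp18 and Scg2, genes of dense-core secretory vesicles, with log2 fold changes of 1.93 ± 0.424 and 1.84 ± 0.371 (SE, adjusted p = 0.00221 and 0.000492).

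Xist and the Y-linked genes split the libraries exactly by treatment label. An exchange of 1 library between the groups cannot be told apart, because no label gives the sex of the animals, although 0 of the 5 libraries had the state of the other group. Genes that escape X inactivation had a median log2 fold change lower than other X genes by a difference of -0.612 (95% interval over genes -1.06 to -0.264), with 6 of 7 lower, which is consistent with female saline and male DTx-labelled animals. Xist was at 172.6 and 128.9 CPM in the saline libraries and at most 0.159 CPM in the DTx-labelled ones. The Y-linked sum was 0.185 and 0.0897 CPM against at least 185.4 CPM. By these genes the saline libraries came from female cells and the DTx-labelled libraries from male cells, so sex and label cannot be separated. A wrong label on all libraries at once, which the Ccr2 counts do not decide, was not tested.

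Interferon response genes were higher in the DTx-labelled libraries. More microglia, which ACSA-2 selection should remove, may account for part of this, since with the microglia marker mean as a covariate the list median was 1.87 (95% interval over genes 0.986 to 2.4) against 2.27 without it. With the monocyte and macrophage marker mean it was 2.65 (1.63 to 3.25), so over genes neither covariate took the pattern away. In a linear model over libraries, the list mean in log2 CPM was higher by 2.03 (95% interval 0.0436 to 4.02, 3 residual degrees of freedom), by 1.64 (-2.51 to 5.78, 2 residual degrees of freedom) with the microglia covariate and by 2.29 (-1.49 to 6.07) with the monocyte one. Both intervals with a covariate include 0, so neither cell type can be excluded as the cause. The tests tried before these gave an interferon minus microglia median of 1.37 (0.413 to 2.21), which was 2.07 and 0.38 (-0.211 to 1.08) without saline replicates 1 and 2 and 0.889 (-0.135 to 1.55) without library 6A. For monocytes and macrophages the difference was 0.476 (-0.488 to 1.85), and was 0.923 and 0.31 without saline replicates 1 and 2, and 1.66 (0.593 to 2.32) and -0.479 (-1.4 to 0.936) without libraries 5A and 6A. Sex cannot be told apart from the toxin, because 5 of 5 libraries had the sex state of their group, and the effect of DTx stays open as a biological explanation.

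The higher hypothalamic genes may come from more hypothalamic tissue in the dissections that gave the DTx-labelled libraries, with neurons that the ACSA-2 selection did not remove. The hypothalamic median exceeded the telencephalic one by 1.39 (95% interval over genes 0.57 to 2.15), and the interval lay above 0 with each library left out, with differences of 0.947 (without 5A) to 2.76 (without saline replicate 2). This goes against more neurons of every region alike, but rests in part on genes of low level. Over genes with a mean of at least 1 CPM the difference was 1.21 (0.149 to 1.85), and its interval lay above 0 without library 6A (1.29, 0.0516 to 1.64) but included 0 without saline replicate 1 (0.43, -0.388 to 1.64), saline replicate 2 (1.94, -0.104 to 3.55), library 5A (0.859, -0.0152 to 2.01) or library 7A (0.837, -0.13 to 2.15). The telencephalic median differed from that of the neuron list by -0.488 (-0.76 to 0.273, over 12 and 19 genes in only 1 of the lists), with an interval below 0 without saline replicate 1 (-0.432, -0.878 to -0.0384) and without library 5A (-0.504, -0.975 to -0.0624), and a difference of -0.25 (-0.685 to 0.401) without saline replicate 2. More neurons of every region therefore cannot be told apart from more hypothalamic tissue. These intervals treat genes as independent, which genes of one tissue are not, and regulation of these genes by treatment or sex was not tested.

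The 10 splits of the 5 libraries into 3 and 2 are too few for a share under 0.05. The real split called 5 genes and the highest other 284. Of the 10 splits 3, the real one included, called at least 5 genes. Another of these set saline replicate 1 and DTx library 5A against the rest and called 101. The split with 284 genes set DTx libraries 5A and 6A against the rest. This points to a structure of the samples other than the groups. Libraries 5A and 6A had the lowest oligodendrocyte marker means (9.42 and 9.37 log2 CPM, against 10.1 and 10.6 in saline and 10.4 in 7A). They had the highest hypothalamic means (2.52 and 2.22, against 0.0475 and 0.752 in saline and 1.18 in 7A). The highest rank correlation between libraries crossed the groups, between saline replicate 2 and library 7A (Spearman 0.9882). Whether cell or tissue composition accounts for this split was not tested. For gene lists the real split and the highest other each called 16, and 2 of the 10 splits, the real one included, gave as many.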
